A study of Mus musculus with 12 samples.

How the data were processed

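The series holds 12 ATAC-seq libraries of mouse bone marrow derived macrophages, in 6 groups of 2 libraries: diabetic and healthy cells in the first phase, and diabetic-trained and untrained cells in the rest and second phases. Per the labels, diabetes was induced in male mice aged 8 weeks with streptozotocin (42 to 45 mg/kg daily for 5 days). Mice above 16.9 mmol/L blood glucose were kept hyperglycaemic for 6 weeks before marrow was taken. Rest-phase cells were cultured for 7 days with M-CSF in 5 mmol/L glucose, and second-phase cells were then stimulated for 16 hours with IFN-γ (10 ng/mL) and LPS (100 ng/mL). The labels do not say when first-phase cells were collected, nor whether 2 libraries of a group come from separate animals. The p-values of single peaks therefore measure only the spread between libraries, which may be technical. Those of gene lists measure the spread between genes, and those of promoter shares that between peaks.

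Per the submitters' processing notes the genome build was mm10, and the tools named are Bowtie2 2.5.4, Picard 3.2.0, MACS2, deepTools 3.2.1, bedtools 2.28.0, DiffBind 3.14.0, DESeq2 and HOMER 5.1. The role of each is not given in the sources used here. The authors deposited 1 table per phase, each with the same 139999 peaks, of which 99.8% are 400 bp wide and the widest 1106 bp. In each table the deposited columns hold the log2 mean of normalized reads of either group, a log2 fold change that is shrunken towards 0, a p-value, an adjusted p-value and the nearest gene. The headers do not tie the mean columns to diabetic or control cells. No value or order was used to guess this, and the groups are called A (first mean column) and B. The deposited fold follows A minus B in the rest phase and B minus A in the first and second phases, and was turned to A over B here. For the second phase, 38000 mostly low peaks are listed at an adjusted p of 1, and the adjustment runs over the other 101999. In the second-phase counts and shares of gene lists, and of random lists, these 38000 stand among the peaks not passing.

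The tables hold group means only. A group mean of 2 libraries is the average of 2 whole read numbers, each times the scaling factor of its library. All group means above the floor were solved for exactly 1 pair of whole numbers, with a largest relative miss of 3.49e-09. This gave reads for all 12 libraries in 139557 peaks, and 442 peaks with a listed 0 were left out of the tests on reads. Libraries are numbered 1 and 2 by the worth of a read and are not tied to the replicate numbers of the labels. On simulated data (20000 peaks) the recovery solved and matched 100% of values.

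Depth in peaks per library (A1, A2, B1, B2) was 4181185, 4392655, 9062119 and 6123193 reads in the first phase, 18617444, 16002834, 5459236 and 8775958 in the rest phase, and 17994363, 10299555, 3832347 and 6075270 in the second. The median peak held 9, 9, 20 and 17 reads in the first phase, 56, 50, 18 and 24 in the rest phase, and 52, 28, 18 and 18 in the second. Total library sizes are not given in the sources used here. Library pairs were compared by the variance of the split of reads between them over that of sampling noise, in peaks with at least 20 reads and with at least 400. The first-phase pair of group A differed by little more than the sampling noise and was counted as 1 sample where phases are compared. Tables within a phase treat it as 2, as the authors did.

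Within each phase, changed peaks are the authors' deposited calls at an adjusted p under 0.05, as fixed before the data were examined for tables that hold only the authors' comparison. The 20 gene lists, the list test, the rule for named genes and most of the alternative settings were also fixed before the data were examined. All tests on recovered reads, and both comparisons between phases, were chosen after the data were seen. They became possible because the recovered reads precede the separate scaling of each table and could be scaled together. Reads were quantile-scaled over the libraries of each comparison and tested on log2 (value + 1) with limma 3.58.1 (empirical Bayes with a trend on signal) and Benjamini-Hochberg adjusted p-values: the rest phase (n = 4) against the first phase (n = 3), and the second phase (n = 4) against the rest phase (n = 4), each with groups A and B pooled. Log2 levels given for single libraries were quantile-scaled over all 12 libraries instead. Alternatives were the authors' scaling and total reads in peaks. All splits of the libraries into groups of the same sizes were run as a permutation check.

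In a test on simulated data with 200 planted peaks among 139557, limma called 0% of 2-fold and 0% of 4-fold changes in the first phase. It called 0% and 73.5% in the rest phase, 0% and 62.0% in the second phase, 10.0% and 94.0% for the rest against the first phase, and 26.0% and 99.0% for the second against the rest phase, with at most 4 false calls. The simulated reads had the same fixed spread in every phase, while the variance ratios of real pairs ran from 1.10 to 15.2. The shares called need not hold for the real libraries. The list test, on 20 simulated lists, called 2 of 2 planted lists (shift 0.4) and 1 of the other 18.

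Peaks were linked to 19395 genes by the nearest gene the tables give. Each list was tested by the median over its genes of the mean log2 fold of their peaks, and by the share of peaks past the threshold, against 10000 random gene lists matched on peaks per gene and mean signal (5 bins each). The test is a two-sided permutation test with Benjamini-Hochberg adjustment over the 20 lists. The lists are acyl-CoA synthetases and fatty acid transport proteins, fatty acid synthesis and desaturation, fatty acid oxidation, triglyceride storage and lipolysis, cholesterol synthesis and efflux, glycolysis and glucose uptake, osteoclast differentiation and resorption, classical inflammatory activation, interferon response, alternative activation, macrophage core, chromatin enzymes of trained immunity, markers of neutrophils, B cells, T and NK cells, erythroid and megakaryocyte cells, stem and progenitor cells, stromal, osteoblast and fat cells, and dendritic and mast cells, and housekeeping genes. Counts adjusted over the list alone repeat the Benjamini-Hochberg step on the peaks of that list.

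Genes are named by a rule: per comparison, the 8 largest folds in each direction among changed peaks with a mean signal at or above the median and a named gene, 1 peak per gene. Added to these are the Acsl1 peak nearest its start, its peak with the smallest p, and up to 4 members of each list by the smallest p. Some genes met by this rule are not reported here by name, though their peaks stay in all counts and list tests. Promoter shares were compared by Fisher's exact test, with unchanged peaks taken from those tested. Overlaps between phases pair identical peaks, and the overlap of independent calls is taken over peaks tested in both tables. The difference between phases was tested with a z score from the difference of deposited means and the standard error its p-value implies, and assumes that A is the same group in both tables.

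Alternatives tried were an adjusted p under 0.01 or 0.10, a log2 fold of at least 1, peaks at or above the median signal, folds centred on their median, a pseudocount of 0.1, each library left out in turn, and for lists promoter peaks within 1 kb, peaks within 50 kb, unmatched random lists and the peak with the highest signal. The software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3. Motifs were not analysed here, since no genome sequence was at hand.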

Results

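Chromatin accessibility was mapped by ATAC-seq in macrophages grown from the bone marrow of mice made diabetic with streptozotocin and of control mice. The cells were collected in a first phase, in a rest phase after 7 days with M-CSF in 5 mmol/L glucose, and in a second phase after a further 16 hours of stimulation with IFN-γ (10 ng/mL) and LPS (100 ng/mL). Each phase holds a diabetic or diabetic-trained group and a healthy or untrained group, with n = 2 libraries per group. The deposited tables do not say which of their 2 mean columns is the diabetic group. The groups are therefore called A (the first mean column) and B, and group A of one phase need not be group A of another. Every fold below is given as A over B within a phase, or as the later over the earlier phase.

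The 12 libraries differed in reads in peaks, which depend on sequencing depth and on the share of reads that fall in peaks. Total library sizes are not given, so the 2 cannot be told apart. Reads in peaks, recovered from the deposited group means, ran from 3832347 in second-phase library B1 to 18617444 in rest-phase library A1. In the rest phase, group A held 18617444 and 16002834 reads in peaks and group B 5459236 and 8775958. The second-phase libraries held 17994363 and 10299555 in group A, and 3832347 and 6075270 in group B. The 2 first-phase libraries of group A differed by little more than sampling noise (variance ratio 1.10, and 1.08 in peaks with at least 400 reads), while the other 5 pairs of a group had ratios of 1.39 to 15.2. Where phases are compared, this pair is counted as 1 sample.

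**Figure D1:**
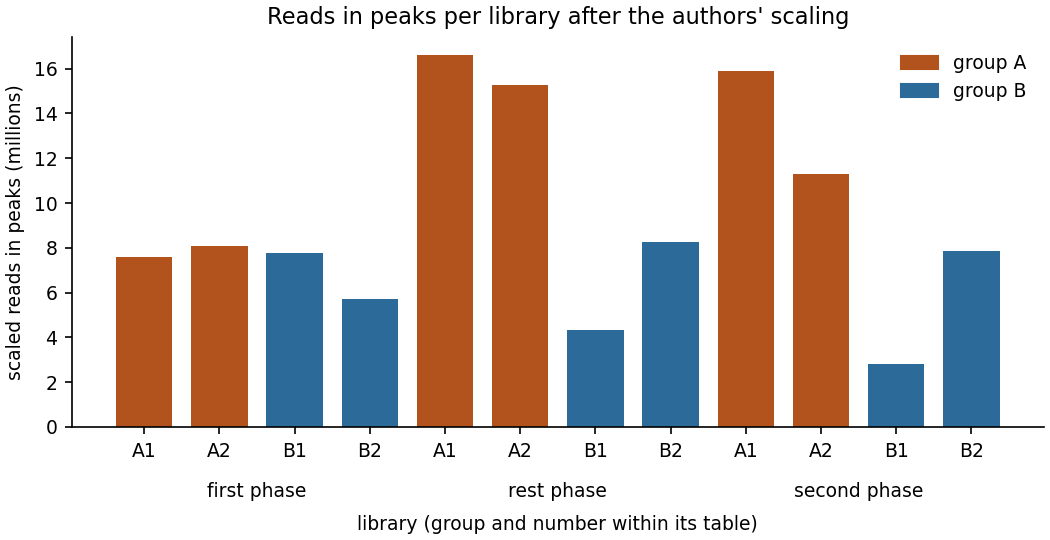
Recovered reads in peaks after the authors' scaling (1e6 scaled reads, y axis) for each of the 12 libraries (x axis: library within group A or B of each phase). The highest value, 16.6, is that of rest-phase library A1 and the lowest, 2.82, that of second-phase library B1.

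In the first phase, no peak and no named gene differed between the groups at an adjusted p under 0.05. Acsl1, the long-chain acyl-CoA synthetase of the study's title, had log2 group means of 10.39 (A) and 9.92 (B) at the peak over its start in the authors' deposited table, with a shrunken log2 fold of 0.0012 and adjusted p = 1.00. The authors' shrinkage brought the log2 folds of the named genes close to 0 in this table, so these do not measure small differences. A peak near Scd1, a fatty acid desaturase, had log2 group means of 4.45 (A) and 2.84 (B) in the authors' deposited table beside a shrunken fold of 0.0035, and one near Il1b, an inflammatory cytokine, 5.70 and 4.23 beside 0.0045. limma with quantile scaling gave 1.55 (SE 0.37) at Scd1 and 1.29 (SE 0.37) at Il1b, each with adjusted p = 0.987 and n = 2 and 2. All tests within this phase count the pair of group A as 2 libraries, though it differed by little more than sampling noise. A peak of Acsl4, an acyl-CoA synthetase for polyunsaturated fatty acids, is listed at 0 in A and at 2.55 in B in the authors' deposited table. None of the 20 gene lists had a peak past the threshold, over all peaks or adjusted over the list alone. The neutrophil markers lay below matched random gene lists (median fold -0.00027 against 0.00033, adjusted p = 0.0040 by permutation), and the genes of classical inflammatory activation above them (0.00041 against 0.00014, permutation p = 0.0050, with an adjusted p just under the threshold). The libraries of the groups interleave in both lists: log2 levels of the neutrophil markers were 6.10 and 6.008 in A, and 5.91 and 6.51 in B, and those of the inflammatory genes 5.26 and 5.08 in A, and 5.00 and 5.25 in B. With limma on quantile-scaled reads both calls were lost (adjusted p = 0.114 and 0.129, in that order). In their place B cell markers (median 0.32, adjusted p = 0.0040 by permutation) and interferon response genes (0.13, adjusted p = 0.0220) lay above random lists. The B cell markers had log2 levels of 5.46 and 5.44 in group A, and of 5.74 and 4.59 in group B, and the interferon response genes 5.36 and 5.46 in A, and 5.38 and 5.28 in B, so the groups interleave in these lists too.

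The authors' deposited table of the first phase holds 0 peaks at an adjusted p under 0.05 and 812 at an unadjusted p under 0.05. limma on the recovered reads also called 0 peaks, with 5360 (the authors' scaling), 6264 (total reads in peaks) and 5120 (quantile scaling) at an unadjusted p under 0.05. Under the authors' scaling limma called 683 peaks without library A1, 553 without A2, 3661 without B1 and 0 without B2, and under quantile scaling 0 whichever was left out. Without B1 or B2 the spread comes from the group A pair alone, which differs by little more than sampling noise, so the 3661 do not show a difference between the groups. In a test on simulated data with the first-phase libraries, limma called 0% of 200 planted changes of 4-fold, so this test excludes no change of that size.

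In the rest phase, 130 peaks were higher in group B, 48.5% of them in distal intergenic regions. Among the 8 named for the largest folds are peaks at Fosb, Egr1, Fos and Jun, immediate early genes that respond within minutes to growth factors and stress. Whether genes of this kind are enriched among the 130 was not tested. Shrunken log2 folds in the authors' deposited table were -3.53 at Fosb (chromosome 7, 19302063 to 19302462), -3.24 at Egr1 (chromosome 18, 34865209 to 34865608), -2.75 at Fos (chromosome 12, 85476050 to 85476449) and -2.42 at Jun (chromosome 4, 95049005 to 95049404). Btg2, an anti-proliferative gene, and Mt2, a metallothionein, stood at -2.98 and -2.39 in the authors' deposited table, followed by Slc7a13 at -2.24 and Dnm3 at -2.13. With limma and quantile scaling the same peaks kept their side, with log2 folds of -4.38 (SE 0.17, n = 2 and 2, adjusted p = 9.98e-05) at Fos, -4.88 (SE 0.20, adjusted p = 9.98e-05) at Egr1 and -5.09 (SE 0.32, adjusted p = 0.000389) at Fosb. Leaving out any 1 library leaves a single one in a group, so such fits cannot decide whether these calls rest on 1 library. The Fos peak had log2 levels of 9.04 and 8.95 in the 2 rest-phase libraries of group B, against 3.98 to 5.76 in the other 10 libraries of the series.

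Among the peaks higher in group A in the rest phase, the largest lay upstream of Il27, a cytokine of activated myeloid cells (chromosome 7, 126598935 to 126599334, 3.91, adjusted p = 3.05e-09 in the authors' deposited table). Mrc1, the mannose receptor of alternatively activated macrophages, had an intron peak (chromosome 2, 14210718 to 14211117) at 3.31, adjusted p = 2.21e-05 in the authors' deposited table. The other 6 among the largest, in the authors' deposited table, lay near Cemip2 (3.42), Ppm1l (3.36), Vwa8 (3.32), Rapgef2 (3.30), Cdk17 (3.29) and Tns3 (3.28). limma with quantile scaling gave 3.36 (SE 0.25, adjusted p = 0.000737) at Il27 and 3.22 (SE 0.27, adjusted p = 0.000887) at Mrc1, with n = 2 and 2.

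Acsl1 stood at a shrunken log2 fold of 0.50 at its start peak (chromosome 8, 46470652 to 46471051; adjusted p = 0.418) and at 1.94 in its intron peak with the smallest p (46501031 to 46501430; adjusted p = 0.0017), in the authors' deposited table of the rest phase. limma with quantile scaling called neither peak (-0.29, SE 0.11, adjusted p = 0.123, and 1.01, SE 0.34, adjusted p = 0.0852), and scaling to total reads in peaks turned the start peak to -0.75 (adjusted p = 4.03e-06). Of the 23 peaks assigned to Acsl1, 8 were higher in group A and 0 in group B in the authors' deposited table, and 1 was higher with limma and quantile scaling.

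Most lipid lists had folds like those of all peaks in the rest phase, whose median shrunken log2 fold in the authors' deposited table was 1.04. Acyl-CoA synthetases and fatty acid transport proteins had 90 peaks higher in A, 0 in B and 105 not passing (92 higher when adjusted over the list alone), led in the authors' deposited table by Fabp4 (a fatty acid binding protein, 2.79), Acsbg1 (2.73), Cd36 (a scavenger receptor, 2.97) and Acsl3 (2.51). Fatty acid synthesis and desaturation had 111 higher, 0 lower and 119 not passing (119 higher adjusted over the list alone), with Acaca, the acetyl-CoA carboxylase, at 2.52, Fads1 at 2.72 and Scd1 at 2.75 in the authors' deposited table. Triglyceride storage and lipolysis had 124 higher, 1 lower (Lpin1, seen after its values) and 141 not passing (132 and 1 adjusted over the list alone), with the lipoprotein lipase Lpl at 2.92 and the fat cell regulator Pparg at 2.49 in the authors' deposited table. Cholesterol synthesis and efflux had 104 higher and 132 not passing (105 adjusted over the list alone), with the efflux pump Abca1 at 2.72 in the authors' deposited table. Against matched random lists none of these 4 stood out by permutation. Median folds were 0.96 against 0.98 (adjusted p = 0.833) for acyl-CoA synthetases and 1.07 against 1.03 (0.736) for synthesis. They were 1.01 against 1.01 (0.956) for triglycerides and 1.02 against 1.06 (0.736) for cholesterol.

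Fatty acid oxidation had a smaller share of deposited calls than matched random lists, which quantile scaling did not bear out: 40 higher, 0 lower and 115 not passing (35 adjusted over the list alone), or 25.8% against 40.6% in matched random lists (adjusted p = 0.0320 by permutation). Its median fold did not differ (0.92 against 0.99, adjusted p = 0.641). Members past the threshold in the authors' deposited table were Slc25a20, the carnitine carrier (2.37), Hadha, of the mitochondrial trifunctional protein (2.29), and the nuclear receptor Ppard (2.03). With limma and quantile scaling 10.3% of its peaks changed against 13.2% in random lists (adjusted p = 0.439). There 3 of its peaks were higher in A and 13 in B, against 21 and 8 for acyl-CoA synthetases, 31 and 9 for fatty acid synthesis, 37 and 9 for triglyceride storage and 18 and 10 for cholesterol. Other lists leaned to B as well, with 4 and 21 for housekeeping genes, 6 and 15 for T and NK cell markers and 2 and 10 for neutrophil markers.

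Alternative activation and macrophage core genes lay above matched random lists in the rest phase, and B cell markers below them. Alternative activation had a median log2 fold of 1.29 against 1.05 (adjusted p = 0.0080 by permutation), with 183 peaks higher, 0 lower and 174 not passing (205 adjusted over the list alone). Its members in the authors' deposited table included the growth regulator Myc (3.09) and Egr2 (2.78), a regulator of alternative activation. The macrophage core had 1.27 against 1.11 (adjusted p = 0.0480), with 196 higher, 0 lower and 170 not passing (219 adjusted over the list alone). Its members in the authors' deposited table included Fcgr1, an Fc receptor (3.23), Adgre1, the F4/80 antigen (2.86), Ccr2 (2.74) and the transcription factor Maf (2.47). B cell markers had 0.51 against 0.80 (adjusted p = 0.0200), with 47 higher, 0 lower and 122 not passing (45 adjusted over the list alone), among them Bank1 (2.69) and Ms4a1, or CD20 (2.60), in the authors' deposited table. With limma folds under quantile scaling all 3 calls were lost (adjusted p = 0.171, 0.186 and 0.171, in the order given). There 48 peaks were higher and 12 lower for alternative activation, 49 and 24 for the macrophage core, and 10 and 8 for B cell markers.

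The remaining lists did not stand out in the rest phase. Osteoclast differentiation and resorption had 320 peaks higher, 3 lower (at Fos and Jun) and 340 not passing (338 and 3 adjusted over the list alone; median 1.11 against 1.10, adjusted p = 0.956). Its members in the authors' deposited table included Prdm1 (2.79), Irf8, a repressor of osteoclast formation (2.58), and Mitf (2.45). Classical inflammatory activation had 146 higher and 249 not passing (140 adjusted over the list alone; 1.00 against 1.03, adjusted p = 0.763), with Acod1, which makes itaconate, at 2.78 and the IL-12 subunit gene Il12a at 2.62 in the authors' deposited table. Interferon response had 74 higher and 151 not passing (66 adjusted over the list alone; 0.97 against 0.98, adjusted p = 0.956), with Ifit2 at 3.15 in the authors' deposited table. Glycolysis and glucose uptake had 107 higher and 174 not passing (107 adjusted over the list alone; adjusted p = 0.733), and chromatin enzymes of trained immunity 315 and 355 (330 adjusted over the list alone; adjusted p = 0.229). In the authors' deposited table Pdk1, which holds back pyruvate oxidation, stood at 2.54, the DNA demethylase Tet2 at 2.85 and the histone methylase Kmt2c at 2.83. With limma and quantile scaling 63 peaks were higher and 44 lower for osteoclast genes, and 51 and 43 for chromatin enzymes. The counts were 35 and 13 for inflammatory activation, 7 and 9 for interferon response and 13 and 18 for glycolysis.

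Markers of other marrow cells were also mostly higher in group A or unchanged in the rest phase. Neutrophil markers had 34 higher, 2 lower (S100a9 and Padi4) and 102 not passing (adjusted p = 0.108), T and NK cell markers 43, 2 (one of them Lef1) and 122 (0.641), and erythroid and megakaryocyte markers 60, 1 (Vwf) and 92 (0.641). Stem and progenitor markers had 109, 0 and 176 (adjusted p = 0.733), stromal, osteoblast and fat cell markers 106, 0 and 163 (0.747), dendritic and mast cell markers 88, 1 (Ccr7) and 86 (0.641), and housekeeping genes 44, 0 and 73 (0.166). The lower members in brackets were named after their values were seen.

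The authors' deposited table of the rest phase calls 55765 peaks, 55635 higher in A and 130 in B (99.8% higher in A). That split rests on the scaling: limma called 77236 (76593 in A, 643 in B) under the authors' scaling, 29911 (61.3% in A) scaled to total reads in peaks and 16537 (53.6% in A) under quantile scaling, which holds the split near even by construction. The median log2 fold of all peaks was 1.31, -0.06 and -0.02 in that order. With the deposited folds centred on their median, 77 peaks passed (13 in A, 64 in B). When any 1 library was left out, a group held a single library, so the number of calls left does not show what rests on that library. Promoters made up 23.8% of the peaks higher in A against 27.7% of unchanged peaks (odds ratio 0.818, p = 1.25e-57 by Fisher's exact test across peaks), with an odds ratio of 0.404 among peaks at or above the median signal.

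**Figure D2:**
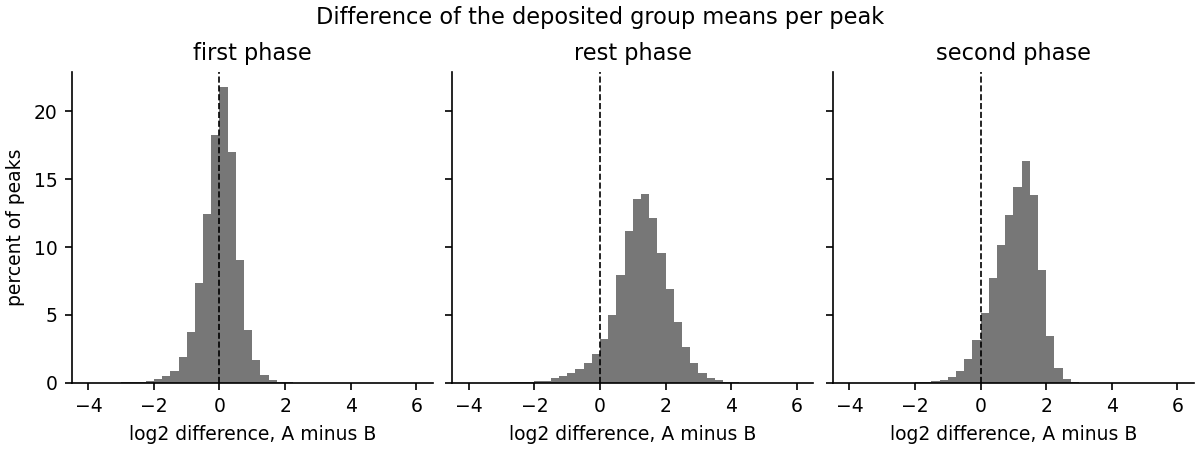
Percent of peaks (y axis) by log2 difference of the deposited means, group A minus group B (x axis), in each phase. The median of all peaks lies at 0.05 in the first, 1.29 in the rest and 1.14 in the second phase.

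In the second phase, after IFN-γ and LPS, the deposited calls again lie in group A. Fewer of them lie at interferon response genes than at matched random genes. Under quantile scaling limma called no peak, so this share could not be tested, and the lower median fold lost its call (adjusted p = 0.125 by permutation). The libraries of either group differ more in these genes (log2 levels of 4.99 and 6.24 in A, 4.87 and 6.22 in B) than the groups do. The largest shrunken log2 folds in the authors' deposited table, all with adjusted p = 0.0242, were at Ttc3 (chromosome 16, 94370540 to 94370939, promoter, 2.44), Lhfpl2 (2.31), Prkch, a protein kinase C (2.25), Chn2 (2.24), Rab4a (2.23), Zswim6 (2.23), Arhgef1 (2.22) and Pld4 (2.21). Interferon response genes had a median log2 fold of 0.61 against 0.96 in matched random lists (adjusted p = 0.0013 by permutation) and 11.6% of peaks higher in A against 35.5% (adjusted p = 0.0040): 26 higher, 0 lower and 199 not passing, and 4 adjusted over the list alone. These 4, in the authors' deposited table, were Mx1 (1.87), Ifit2 (1.73), Zbp1, a sensor of nucleic acids (1.69), and the GTPase gene Irgm2 (1.59). Classical inflammatory activation lay at 0.77 against 0.95 (adjusted p = 0.0013), with 97 higher, 0 lower and 298 not passing (0 adjusted over the list alone), among them Il6 (1.70), Il12b (1.65) and Cfb, complement factor B (1.48), in the authors' deposited table.

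A further 4 lists differed from random lists in the second phase. Glycolysis and glucose uptake lay at 0.80 against 0.96 (adjusted p = 0.0013; 68 higher, 213 not passing, 20 adjusted over the list alone), with the fructose bisphosphate regulators Pfkfb4 at 1.92 and Pfkfb3 at 1.62 in the authors' deposited table. B cell markers lay at 0.45 against 0.61 (adjusted p = 0.0340; 21 higher, 148 not passing, 0 adjusted over the list alone) and housekeeping genes at 0.78 against 0.96 (adjusted p = 0.0152; 24 higher, 93 not passing, 14 adjusted over the list alone). Macrophage core genes lay above, at 1.09 against 0.94 (adjusted p = 0.0040; 163 higher, 203 not passing, 179 adjusted over the list alone). Examples in the authors' deposited table were Mertk, a receptor for apoptotic cells (2.00), and the lysosomal proteases Ctsd (1.84) and Ctsb (1.83). With limma folds under quantile scaling only the inflammatory list kept its call (-0.08 against 0.05, adjusted p = 0.0040). Its log2 levels were 5.01 (A1), 5.83 (A2), 5.00 (B1) and 5.98 (B2), so the libraries of either group differ by more than the groups. The other 5 lost it (adjusted p = 0.125 for interferon, 0.183 for glycolysis, 0.935 for B cell markers, 0.290 for housekeeping and 0.183 for macrophage core).

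Lipid genes did not stand out in the second phase. Acyl-CoA synthetases had 50 peaks higher, 0 lower and 145 not passing (48 adjusted over the list alone; median 0.85 against 0.79, adjusted p = 0.570), with Acsl3 at 1.87 and the fatty acid transporter gene Slc27a1 at 1.65 in the authors' deposited table. Fatty acid synthesis had 70 higher and 160 not passing (65 adjusted over the list alone; 0.96 against 0.85, adjusted p = 0.0954), with the desaturase gene Fads3 at 1.84 and the elongase gene Elovl5 at 1.75 in the authors' deposited table. Acsl1 had 4 of 23 peaks higher in A, with 1.05 (adjusted p = 0.0709) at its start and 1.41 (adjusted p = 0.0244) at an intron peak (46508502 to 46508901) in the authors' deposited table. Triglyceride storage had 102 higher, 1 lower (Mgll, seen after its values) and 163 not passing, and osteoclast genes 214, 0 and 449, with the proton pump subunit gene Atp6v0d2 at 1.99 and Nfatc1 at 1.79 in the authors' deposited table. Peaks higher in A numbered 37 for fatty acid oxidation, 81 for cholesterol, 125 for alternative activation, 206 for chromatin enzymes, 35 for neutrophil, 24 for T and NK cell, 47 for erythroid, 62 for stem, 57 for stromal and 45 for dendritic and mast cell markers. These 10 lists, triglyceride storage and osteoclast genes had adjusted p of 0.103 to 0.978 for the median fold, by permutation. For the share of changed peaks their lowest adjusted p were 0.0873 (triglyceride storage) and 0.0874 (neutrophil markers).

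The authors' deposited table of the second phase calls 37374 peaks, 37368 higher in A and 6 in B, with 59927 at an unadjusted p under 0.05. limma called 0 under each scaling, with 5331 (the authors' scaling), 1356 (total reads) and 1046 (quantile) at an unadjusted p under 0.05. The median log2 fold of all peaks was 1.14, -0.31 and 0.01 under these scalings. Without library B2 limma under the authors' scaling called 15534 peaks, without A2 69, and without A1 or B1 0. Promoters made up 35.0% of the peaks higher in A against 28.1% of tested unchanged peaks (odds ratio 1.38, and 1.19 among peaks at or above the median signal).

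From the first to the rest phase, regions at neutrophil, B cell and erythroid marker genes became less open and regions at macrophage genes more open. A promoter peak of S100a9, a calcium-binding protein of neutrophils (chromosome 3, 90695611 to 90696010), fell by 6.39 on the log2 scale (SE 0.38, n = 4 and 3, adjusted p = 3.05e-07 by limma). Neutrophil granule gene Ngp fell by 5.59 (SE 0.36, adjusted p = 4.36e-07), the granulocyte regulator Cebpe by 4.38 (SE 0.32, adjusted p = 9.07e-07) and the chemokine receptor Cxcr2 by 4.65 (SE 0.36, adjusted p = 1.20e-06). Folr2, a folate receptor of tissue macrophages (chromosome 7, 101853854 to 101854253), rose by 4.83 (SE 0.29, adjusted p = 3.00e-07), Gas6, a ligand for the clearance of dead cells, by 3.89 (SE 0.20, adjusted p = 1.52e-07), the complement gene C1qc by 3.16 (SE 0.23, adjusted p = 8.34e-07) and the M-CSF receptor gene Csf1r by 3.11 (SE 0.29, adjusted p = 4.24e-06). The values do not separate a change in the mix of cells from a change within macrophages. How the first-phase cells were collected is not stated in the labels, and any batch shared by the libraries of a phase cannot be told from the phase.

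All 21 neutrophil genes had a peak that fell: 5 peaks rose, 100 fell and 33 did not pass (6 and 102 adjusted over the list alone), with a median log2 fold of -1.89 against -0.04 in matched random lists (adjusted p = 0.0013 by permutation). B cell markers had 19 up, 69 down and 81 not passing (20 and 73 adjusted over the list alone; median -1.43, adjusted p = 0.0013), with Cd72 at -3.72 (SE 0.31) and the surrogate light chain gene Igll1 at -3.59 (SE 0.34), while Il7r, the IL-7 receptor gene, stood at 2.93 (SE 0.20). Erythroid and megakaryocyte markers had 27 up, 59 down and 66 not passing (31 and 60 adjusted over the list alone; median -0.85, adjusted p = 0.0013), led by the haem enzyme gene Alas2 at -4.74 (SE 0.42) and the platelet gene Gp9 at -3.69 (SE 0.32). T and NK cell markers had 24 up, 62 down and 81 not passing (25 and 65 adjusted over the list alone), a larger share than in random lists (51.5% against 36.8%, adjusted p = 0.0008), with Tcf7 at -3.55 (SE 0.37). Their median of -0.34 did not pass (adjusted p = 0.0547).

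Macrophage core genes had 112 peaks up, 44 down and 210 not passing (113 and 46 adjusted over the list alone), with a median log2 fold of 0.39 against -0.04 (adjusted p = 0.0040 by permutation). Interferon response genes had 20 up, 76 down and 129 not passing (25 and 79 adjusted over the list alone; median -0.42, adjusted p = 0.0144), with the antiviral gene Oasl2 at -5.42 (SE 0.45), Ifit1 at -3.33 (SE 0.32) and the immunoproteasome gene Psmb9 at -2.75 (SE 0.25), while the inhibitor Socs1 stood at 2.64 (SE 0.23). This call was lost under the authors' scaling (adjusted p = 0.0685) and total reads (adjusted p = 0.0543). Alternative activation (104 up, 48 down, 204 not passing, 112 and 48 adjusted over the list alone) had a median of 0.29 (adjusted p = 0.0605), with Egr2 at 2.92 (SE 0.24) and the IL-4 receptor gene Il4ra at -3.41 (SE 0.26).

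Lipid genes moved both ways between the first and the rest phase. Triglyceride storage had 71 peaks up, 75 down and 120 not passing (73 and 78 adjusted over the list alone), 54.9% changed against 40.9% in random lists (adjusted p = 0.0008). Mgll, the monoacylglycerol lipase, stood at -5.43 (SE 0.32), Agpat4 at -4.46 (SE 0.40), the lipase inhibitor G0s2 at -3.91 (SE 0.39) and the droplet coat gene Plin2 at 2.61 (SE 0.24). Fatty acid oxidation changed less, with 15 up, 25 down and 115 not passing (12 and 24 adjusted over the list alone; 25.8% against 39.9%, adjusted p = 0.0027). Acyl-CoA synthetases had 51 up, 37 down and 106 not passing (51 and 37 adjusted over the list alone). Their median was -0.14 (adjusted p = 0.439 by permutation), with Cd36 at 3.62 (SE 0.29), Acsl4 at 4.06 (SE 0.34) and Fabp5 at -3.77 (SE 0.30). With promoter peaks only, this list lay above random lists (adjusted p under 0.05 by permutation). Acsl1 was less open at 14 of its 23 peaks and more open at 1, in a comparison where neutrophil and B cell markers fell too, so a change in the mix of cells would also change this count. Its start peak stood at -0.25 (SE 0.15, adjusted p = 0.211; -1.03, adjusted p = 0.0039, scaled to total reads) and a peak near its 3' end (46533897 to 46534296) fell by 2.88 (SE 0.26, adjusted p = 3.75e-06). Fatty acid synthesis had 39 up, 37 down and 154 not passing (38 and 37 adjusted over the list alone; adjusted p = 0.442), and cholesterol synthesis and efflux 49, 35 and 152 (adjusted p = 0.439), with Abca1 at 3.17 (SE 0.25) and the lysosomal carrier Npc2 at 3.03 (SE 0.23).

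Osteoclast genes had 151 peaks up, 140 down and 372 not passing (153 and 142 adjusted over the list alone; median 0.06, adjusted p = 0.457), with the collagenase gene Ctsk at 2.65 (SE 0.17), Trem2 at 2.67 (SE 0.21) and Mmp9 at -3.87 (SE 0.31). Glycolysis had 42 up, 74 down and 165 not passing (42 and 75 adjusted over the list alone; adjusted p = 0.488), with Pfkp at 4.29 (SE 0.29) and Ldha, lactate dehydrogenase, at -4.71 (SE 0.35). Classical inflammatory activation had 95 up, 78 down and 221 not passing (101 and 80 adjusted over the list alone; adjusted p = 0.457), with the chemokine gene Ccl2 at 2.90 (SE 0.19) and Acod1 at -3.05 (SE 0.27). Chromatin enzymes (143 up, 115 down), stem and progenitor markers (50, 65), stromal markers (54, 45), dendritic and mast cell markers (29, 43) and housekeeping genes (16, 32) had adjusted p of 0.977, 0.0715, 0.927, 0.123 and 0.439.

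limma called 53663 of 139557 peaks between the rest and the first phase, 27398 up and 26265 down. The near-even split is fixed by the quantile scaling. The authors' scaling gave 39781 calls (32810 up, 6971 down) and total reads 55485 (36832 up, 18653 down), with the median of all peaks at 0.74 and 0.30. Of the 35 ways to split the 7 libraries, only the real split called so many, and the highest other called 10402. Peaks that fell were richer in promoters than unchanged peaks (37.6% against 24.6%, odds ratio 1.85), and those that rose were poorer in them (20.2%, odds ratio 0.773, p = 3.88e-53 by Fisher's exact test).

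**Figure D3:**
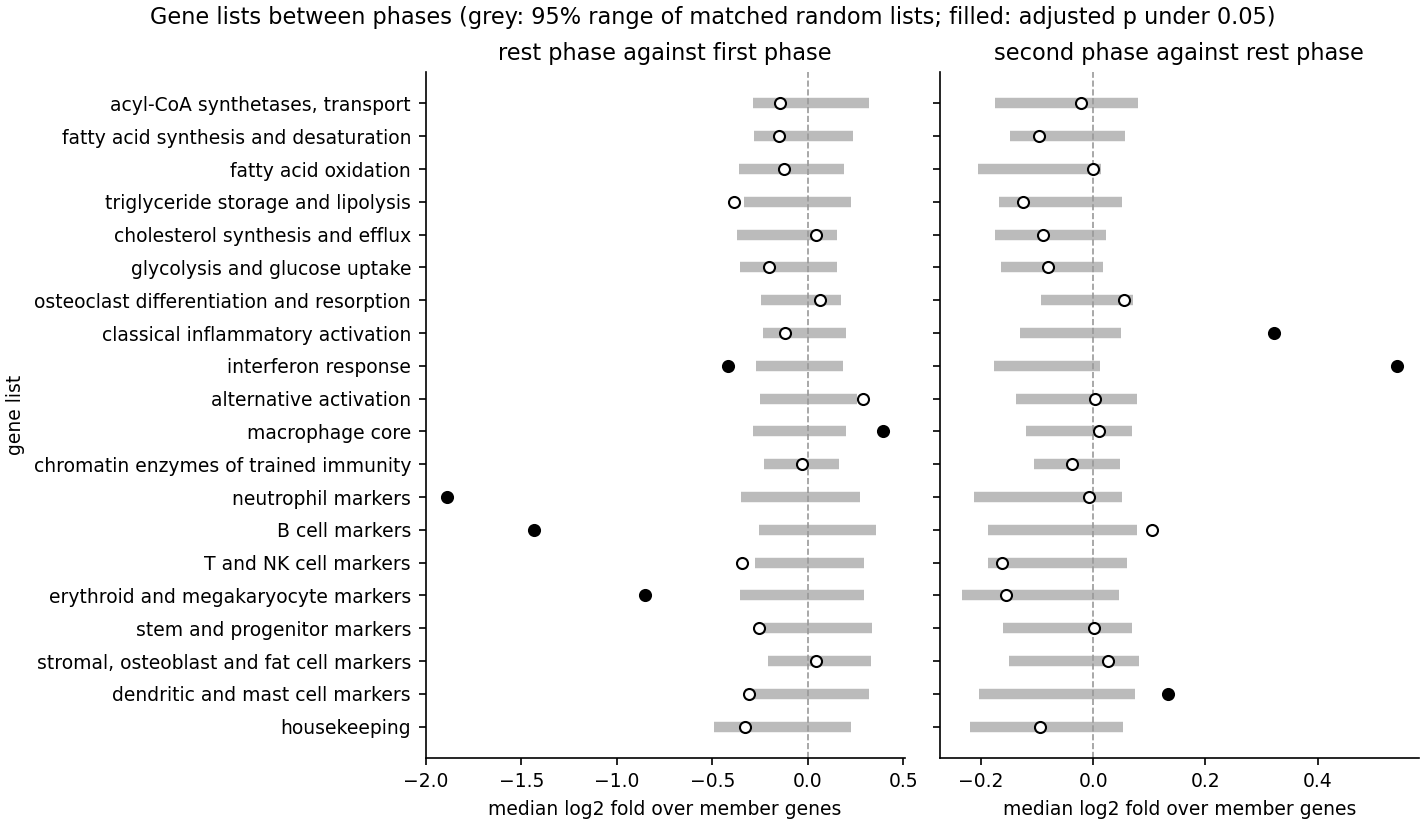
Median log2 fold (x axis) of each gene list (y axis) for the rest over the first phase and the second over the rest phase, with the 95% range of matched random lists in grey. Neutrophil markers lie at -1.89 for the rest phase, and interferon response genes at 0.54 for the second phase.

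Between the rest and the second phase, interferon and inflammatory regions opened as groups, mainly in libraries A2 and B2 of the second phase, although no single peak passed by limma. At interferon response genes second-phase A1 (log2 level 4.99) and B1 (4.87) stood at rest-phase levels (4.87 to 5.04). Interferon response genes had a median log2 fold of 0.54 against -0.09 in matched random lists, and classical inflammatory activation 0.32 against -0.04 (folds from n = 4 and 4 libraries). The adjusted p was 0.0020 for each by permutation over genes, which does not measure the spread between libraries. The interferon median was 0.38 without A2, 0.32 without B2, 0.63 without A1 and 0.78 without B1. Dendritic and mast cell markers had 0.13 against -0.07 (adjusted p = 0.0467), a call lost without second-phase A1 (adjusted p = 0.604) or B1 (0.303), without rest-phase B1 (0.308) or B2 (0.202), and under both other scalings (0.302 and 0.261). Single peaks by limma were at 1.73 (SE 0.40) for the NF-κB inhibitor Tnfaip3, 2.30 (SE 0.56) for the chemokine gene Cxcl1, 1.16 (SE 0.34) for Ifi44, 0.77 (SE 0.21) for the antiviral Oas3 and 0.95 (SE 0.30) for Cd74, which chaperones MHC class II, each with adjusted p = 0.423. No peak of any of the 20 lists passed over all peaks, or adjusted over the list alone. The other 17 lists, lipid and osteoclast genes among them, had adjusted p of 0.115 to 0.949.

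limma called 0 peaks between the second and the rest phase, with 15950 at an unadjusted p under 0.05, a count that depends on the tool and the scaling. Scaling to total reads gave 0 as well (12636 at an unadjusted p under 0.05), and the authors' scaling 189 (187 up, and 2 down near Kazn and an unnamed Riken locus, seen after their values). Among the 187 is an Acsl1 peak upstream of the gene (46406714 to 46407113), at 2.70 with adjusted p = 0.00099 there and at 2.83 (SE 0.69, adjusted p = 0.423) under quantile scaling. A split of these 8 libraries other than by phase called 14825 peaks, which points to a structure of the samples other than phase. Every library is therefore shown on its own. Interferon response genes had log2 levels of 4.87 to 5.04 in the 4 rest-phase libraries, and of 4.99 (A1), 6.24 (A2), 4.87 (B1) and 6.22 (B2) in the second phase.

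**Figure D4:**
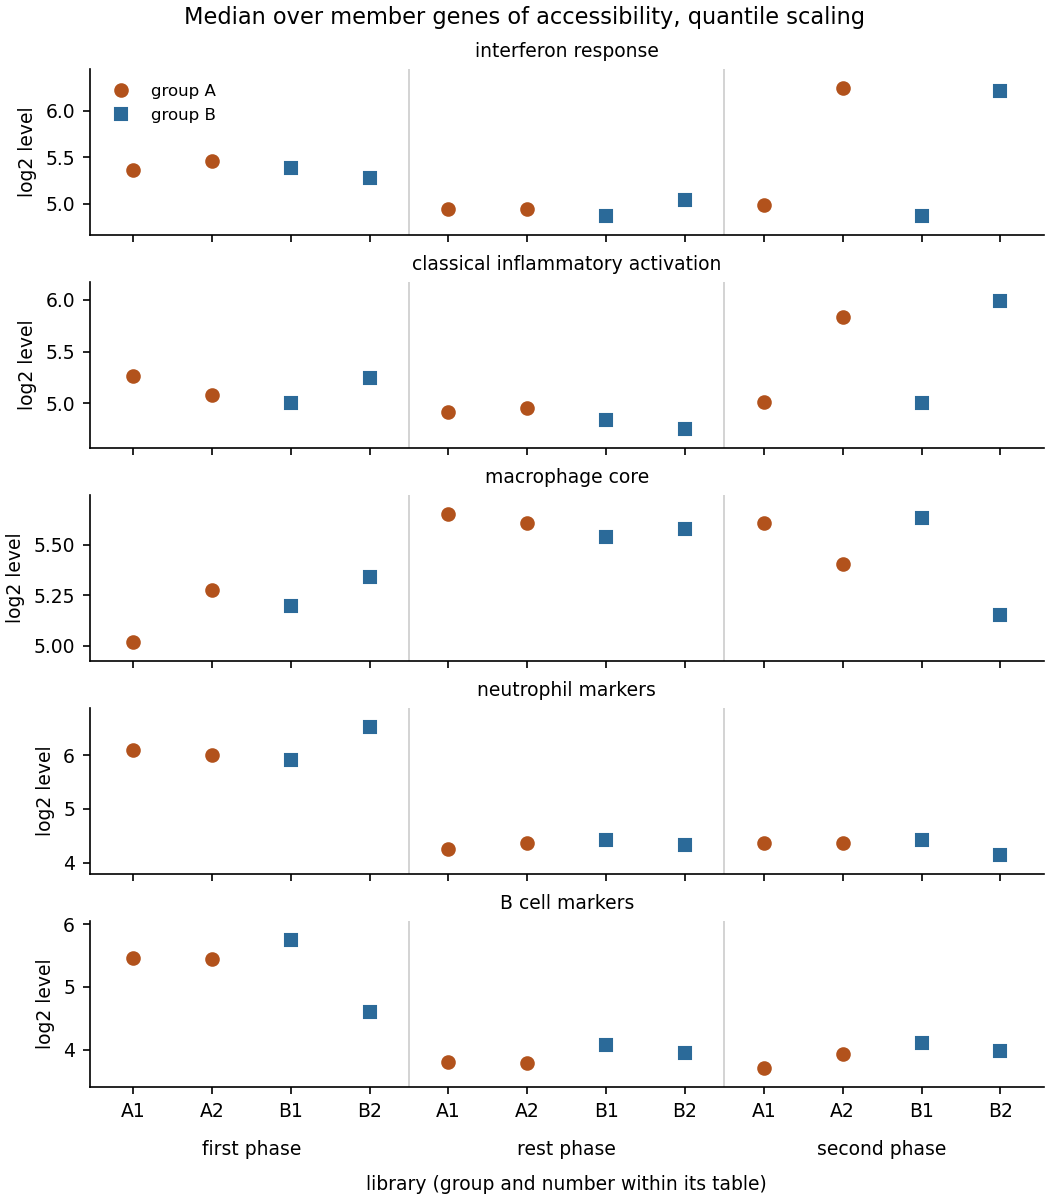
Median log2 accessibility (y axis, quantile-scaled) of 5 gene lists in each of the 12 libraries (x axis), groups A and B by colour and shape. Interferon response genes reach 6.24 and 6.22 in second-phase libraries A2 and B2, against 4.99 and 4.87 in A1 and B1, and neutrophil markers reach 6.51 in the first phase.

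Across the Acsl1 locus on chromosome 8, 14 of the 23 peaks were less open in the rest than in the first phase, as were neutrophil and B cell markers (medians -1.89 and -1.43). Whether the cells of the 2 phases are of the same kinds is not stated in the labels. These peaks are assigned by nearest gene and reach beyond it on either side, so some may serve other genes.

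**Figure D5:**
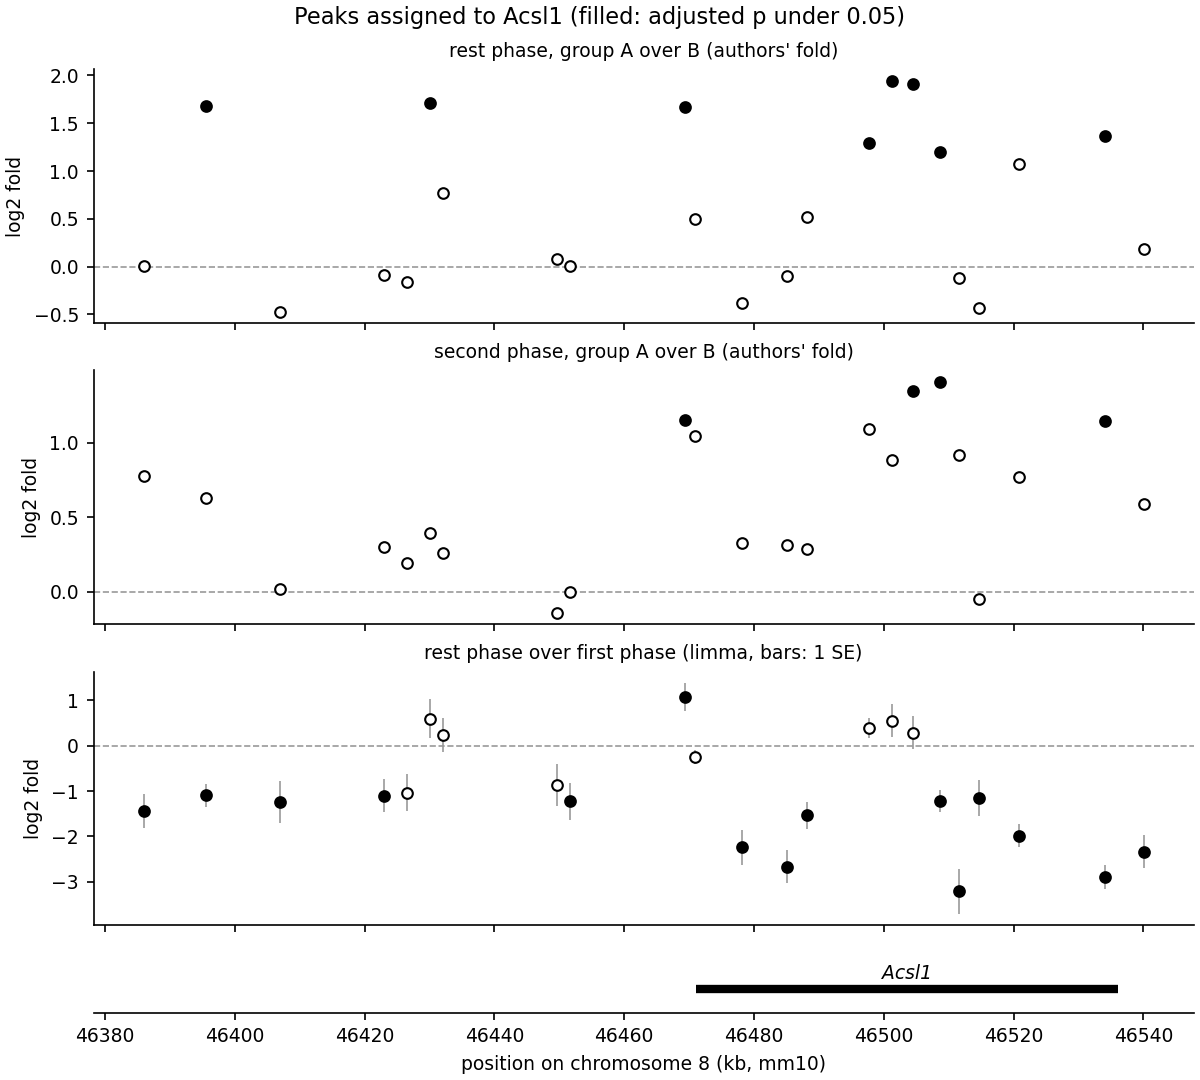
Log2 fold (y axis) of each of the 23 peaks assigned to Acsl1 by position on chromosome 8 (x axis, the gene as a bar), for A over B in the rest and second phases (deposited) and for the rest over the first phase (limma, bars of 1 SE). Filled points have an adjusted p under 0.05: 8, 4, and 15 in the last panel.

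In the authors' deposited tables, a total of 24927 peaks were higher in A in both the rest and the second phase, 0 were higher in B in both and 1 went opposite ways, if group A is the same group in both tables. Independent calls among the peaks tested in both would share 18429.2. That figure takes no account of the shift of all peaks towards A in both tables, and with folds centred on their median the second phase has 0 calls. The Pearson correlation of the log2 folds across peaks was 0.538. The group difference itself, as group A minus group B in the authors' deposited tables, differed between the rest and the first phase at 617 peaks, 614 with a larger and 3 with a smaller value in the rest phase. With folds centred on their median it differed at 4, 0 larger and 4 smaller, so the 614 rest on the shift shared by all peaks of the rest phase. The 3 lie at Fos, Fosb and Btg2, genes named above by the rule. It differed at 0 peaks between the rest and the second phase, and at 0 between the second and the first. If the columns of the later-named table are in the opposite order, the count is 90804 for rest minus second, 1870 for rest minus first and 1 for second minus first.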

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

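Apart from the test of the difference between phases, all tests in this part were chosen only after the results were seen.

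The group difference, A minus B, differed between the rest and the first phase at 617 peaks, a difference between phases found by a direct test. It takes group A as the same group in both tables, and 1870 peaks differ if the columns are in the opposite order. Of the 617, 614 had a larger value in the rest phase. With folds centred on the median 4 peaks differ, 0 with a larger and 4 with a smaller value, so the count and its direction rest on the shift shared by all peaks.

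Nearly all deposited calls of the rest and second phases are higher in group A. If libraries differ in enrichment, 2 libraries of the same group can differ as much as the groups do. In the second phase they did: scaled reads in peaks differed 2.78-fold within group B and 1.41-fold within A, against 2.55 between the groups. In the rest phase the ratios were 1.904 within B and 1.09 within A, against 2.53 between the groups, which decides nothing. A global gain in accessibility, in diabetic or in control cells, would put both libraries of A above both of B, and the lowest of A was 1.85 times the highest of B in the rest phase and 1.44 times in the second, which a difference in library quality gives too. The lopsided calls of the second phase are thus consistent with a difference in enrichment between libraries. For the rest phase that stays open, and in both phases a global biological difference can be neither shown nor excluded. The peaks at Fos, Fosb, Egr1 and Jun run against this shift and kept their call with limma under each of the 3 scalings with all libraries. A fit without 1 library leaves a single one in a group, so such fits cannot decide whether these calls rest on 1 library. At Fos, the levels given above put both rest-phase libraries of group B above all other libraries. Levels per library at the other peaks are not given here.

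The 2 libraries of either second-phase group differ at interferon response genes. Low enrichment in A1 is unlikely, since it held 1.41 times the scaled reads in peaks of the higher of A2 and B2, while B1 held the fewest of all (2.82 in 1e6 scaled reads, against 11.3 in A2 and 7.85 in B2). In B1 it is unlikely as the whole reason, since its correlation with a rest-phase library exceeded that with A2 by 0.131. An exchange with a rest-phase library is also unlikely, as the lower of A2 and B2 lay 1.18 log2 units above the highest rest-phase library. A difference between diabetic and control cells is unlikely if every library lies in its right group, because the groups interleave (gap of -1.23 log2 units). An exchange of libraries between the 2 second-phase groups would also make them interleave, and was not tested. A library without a response, whether unstimulated, unresponsive or wrongly labelled, remains a candidate explanation for A1 and B1, since the higher of the 2 lay at -0.0502 log2 units from the highest rest-phase library.

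The first-phase libraries of group A differ by little more than sampling noise. Low depth is unlikely as the reason, because the other pairs thinned to the same depth had variance ratios of at least 1.29. A single library sequenced or split in 2 parts is a candidate explanation, as the ratio did not grow in peaks with at least 400 reads (1.08). No biological explanation was tested.

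For the rest against the first phase 1 of 35 splits, the real split, called 53663 peaks and the highest other 10402. Since 1 of 35 is the smallest share possible, this makes chance unlikely but cannot exclude it, nor a batch shared by a phase. For the second against the rest phase the splits say nothing about chance: the real split called 0 peaks, so all 35 of 35 splits call at least as many whatever the values. The highest other split called 14825. It sets second-phase A1 and B1 with rest-phase A1 and A2 against the others, and points to a structure of the samples that phase does not capture.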

How the results depend on the processing

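No paired analysis was possible because the columns carry no replicate numbers. Motifs were not run without a genome sequence. A replicate block was not run, since the recovered libraries are not tied to replicate numbers. Count tools, set down for tables of counts per library, were tried after seeing the data but are not reported by value, since the deposited values are log2 group means and the recovered reads were tested on a log scale with limma. DESeq2 with its own size factors did call peaks for the second against the rest phase, where limma with quantile scaling called 0. Tests on recovered reads, the opposite column order and folds of group means were chosen after seeing the data. Where a library is left out of a group of 2, the lone one is assumed to vary like the other groups. The calls of such a fit do not show whether a result rests on the library left out.

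Rest-phase calls (55765) moved to 23195 at an adjusted p under 0.01, 77 centred on the median, and with limma to 29911 scaled to total reads and 16537 under quantile scaling. Leaving out 1 library gave 9275 to 109366 under the authors' scaling (9275 and 12419 without A1 and A2, 109366 without B2), and 0 to 0 under quantile scaling. Second-phase calls (37374) moved to 0 at an adjusted p under 0.01, 61382 under 0.10, 0 centred, and with limma to 0 under the authors' scaling, 0 scaled to total reads, 0 under quantile scaling, 7 with a pseudocount of 0.1 and 0 at or above the median signal. Leave-one-out gave 0 to 15534 (69 without A2) under the authors' scaling and 0 to 0 under quantile scaling. First-phase calls stayed at 0 but for leave-one-out under the authors' scaling (0 to 3661, with 683 and 553 without A1 and A2). The authors' scaling gave 189 calls for the second against the rest phase, from 0. Rest against first (53663) gave 42082 to 55592 leaving out 1 library, 39781 under the authors' scaling (6971 of them down, from 26265) and 36943 among peaks at or above the median signal. The cause was not tested, except that centring takes away the shared shift and a stricter threshold passes fewer peaks.

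The counts of lists given here are calls by the median fold, not by the share of changed peaks. Lists called in the first phase (2) numbered 1 with promoter peaks, 1 within 50 kb, 0 unmatched, 1 with the highest peak and 5 with group means. The rest phase (3) gave 5 unmatched, 5 with the highest peak and 0 under quantile scaling, and the second phase (6) 1 under quantile scaling. Rest against first (5) gave 5 to 9 leaving out 1 library (8 without rest B1, 9 without rest B2, 8 without first B2). All 42 list results followed there kept their call, or their lack of one. In the same comparison 1 list lost its call with promoter peaks only, and 2 with the highest peak. Shared peaks (24928) numbered 0 at an adjusted p under 0.01 and 44526 at an unadjusted p under 0.05. Peaks differing between phases numbered 4 centred and 1870 in the opposite column order for rest minus first, 90804 for rest minus second (0) and 1 for second minus first (0). Acyl-CoA synthetases for the rest against the first phase reversed with promoter peaks only, at 0.68 above random lists. There they passed an adjusted p under 0.05 by permutation, while over all peaks they had no call. Also reversed were the promoter odds ratio of rest-phase peaks higher in B (2.05 at an adjusted p under 0.01, from 0.623) and the Acsl1 start peak in the rest phase (-0.75 scaled to total reads). The cause was not tested. Of 96 named rest-phase results 78 kept their call, or their lack of one, under quantile scaling and 18 lost their call. Among the 78, the Acsl1 start peak changed side (0.50 to -0.29) without a call in either. Of 89 named second-phase results 88 lost their call.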

Other observations

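The correlations and splits in this part are tests chosen only after the results were seen. Acsl1 and the stimulus genes were followed in single second-phase libraries, and the genes named here were chosen after their values were seen. Mean log2 levels over the 23 Acsl1 peaks were 4.17 (A1), 5.96 (A2), 4.55 (B1) and 5.77 (B2), against 4.07 to 4.40 in the 4 rest-phase and 5.18 to 5.31 in the 4 first-phase libraries. The chemokine gene Ccl5 lay at 4.89, 7.13, 4.98 and 7.35 in the same order. The guanylate binding protein gene Gbp4 lay at 3.46, 6.82, 3.56 and 7.14, the prostaglandin enzyme gene Ptgs2 at 2.55, 6.02, 2.86 and 8.05, the nitric oxide synthase gene Nos2 at 4.60, 6.27, 4.58 and 6.81 and Cxcl10, another chemokine gene, at 5.77, 7.98, 5.84 and 8.26.

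The second-phase libraries most alike were of different groups. The Pearson correlation over peaks was 0.936 for A2 with B2 and 0.893 for A1 with B1, against 0.827 within group A and 0.745 within group B, while the other pairs across groups stood at 0.796 (A1 with B2) and 0.767 (A2 with B1). Second-phase A1 correlated at 0.977 with rest-phase A1, the highest value among rest- and second-phase libraries, while rest-phase A1 and A2 stood at 0.968. The variance ratio was 1.88 for second-phase A1 with rest-phase A1, and 3.01 for rest-phase A1 with A2. Among all splits of the 4 libraries into pairs, that of A1 and B1 against A2 and B2 called 26126 peaks with limma and quantile scaling, 20953 scaled to total reads and 431 under the authors' scaling, and the split into groups 0 under each, which points to a structure of the samples other than the groups. First-phase libraries correlated at 0.483 to 0.690 with those of the other phases and at 0.863 to 0.900 among themselves.

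A hypothesis was that the rest-phase group difference lies on the same axis as the differences within second-phase groups. Its prediction was written before the correlations were computed. The rest-phase fold of A over B correlated across peaks at 0.385 with A1 minus A2 and at 0.217 with B1 minus B2 of the second phase. The lower value falls between the limits set for and against a shared axis, so the data do not decide whether there could be one.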
